A study of Mus musculus with 2 samples.

How the data were processed

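RNA of mouse embryos was compared on 2-colour Agilent microarrays with 60-base probes. In each hybridisation, RNA of control embryos and of embryos with a Cdx2 knockdown was labelled with Cy5 and Cy3 and applied to the same array. Per the labels, 8-cell embryos were studied in 2 biological replicates and blastocysts in 3, and each hybridisation was repeated with the dyes exchanged. The 10 arrays therefore held 10 RNA extracts in 5 pairs of 1 control and 1 knockdown extract.

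The deposited scanner files held, per spot, mean spot intensity and median local background intensity in each channel, which the authors obtained with Agilent Feature Extraction (version 7.5 per the submitters' processing notes, A.7.5.1 per the file headers). Per the file headers, the software had also made processed intensities, by removing a spatial background surface and by dye normalization with a LOWESS step, and from them a log10 ratio of Cy5 over Cy3. Per the labels' protocols, RNA was extracted with TriZol and amplified and labelled with a low-input linear amplification kit. The authors also deposited 1 summary value per probe and stage, with scale and direction not given in the sources used here. Set against the scanner files, these values behaved, under the direction taken here, as log10 ratios of control over knockdown: across probes they correlated with the ratios computed here at r = 0.752 for 8-cell embryos, with a slope of 1.39, and at r = 0.807 for blastocysts, with a slope of 1.01. Their medians were -0.000595 and 0. How the authors combined and weighted the arrays is not given in the sources used here, so this table served only as an alternative. No genome build is given in the sources used here and no coordinates are printed.

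The conditions of single arrays were read from the labels, which give control RNA in Cy5 and knockdown RNA in Cy3, and from the order of the conditions in the names of the arrays, which also carry the number of the pair. One label of the blastocysts calls the Cy3 channel wild type while the treatment field of that channel states a knockdown. The direction of all ratios is therefore likely, not settled, and rests on the channel labels and the array names. Exchanging the dyes turned the sign of the ratios in all 5 pairs: as scanned, the arrays of a pair correlated at -0.318 to -0.912 across probes.

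Background was corrected with normexp (offset 50) on mean spot and median background intensity, and arrays were normalized by loess within each array with limma 3.58.1 in R 4.3.3, with control spots and outlier spots given no weight. Outlier spots were then left out, and saturated spots were kept. Ratios were turned to log2 of knockdown over control and averaged over the dye-swapped arrays of a pair; a pair counted for a probe only where both arrays had a usable spot, since a dye effect cancels only then. Of 44290 spots, 2256 were controls, and a further pair of features spotted 98 and 99 times, whose accessions the mouse table does not hold, was left out. The other 41837 spots held 41819 probes. Tested were the 37446 probes that were well above background for at least 1 stage and condition on all of its arrays with a usable spot, and that had at least 1 pair at the 8-cell stage and 2 at the blastocyst stage. The last condition and the need for both arrays were set after the data were seen, and the looser rule is among the alternatives.

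One limma fit (lmFit, eBayes) over the 5 pairs had a mean per stage. Both stages shared 1 estimate of the spread per probe, moderated over probes, so an SE at 1 stage also holds the spread of the other. Each mean was tested against 0, and the difference blastocyst minus 8-cell was tested in the same fit. For the comparison of control blastocysts with control 8-cell embryos, arrays were further normalized with Aquantile, single-channel log2 signals were averaged per extract over its dyes, and the 10 extracts were fitted as 4 groups. All tests were two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05, and every adjusted p-value below comes from these limma fits unless a narrower adjustment is named. A probe that was on no array of a group well above background has only a bound there. In such a case the brighter group was set against the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own signal. The number of arrays limits the precision. The median half-width of the 95% confidence interval was 0.385 on the log2 scale for the 8-cell ratios, 0.317 for the blastocyst ratios and 0.504 for the comparison of control embryos between stages.

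The pairs were formed by hybridising both extracts on the same arrays, so the pair was within the ratio. Deviations from the group means were correlated across probes between control and knockdown extracts of the same number. The correlations were 0.284 to 0.576 in blastocysts and 0.695 in 8-cell embryos. They do not show that the embryos were matched, since both extracts of a pair were read from the same arrays. With 2 pairs, the 8-cell deviations also mirror each other, so both pairs give the same value. Feature Extraction runs fell on 4 days, which served as batches: each 8-cell pair had its own, blastocyst pairs 1 and 2 shared 1, and blastocyst pair 3 had its own. Each array carried both conditions, so the day was balanced between them, but no day held both stages.

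The files name most probes by identifiers of the array design: 36301 probes carried a transcript identifier, 5396 a clone identifier, 102 a GenBank accession and 20 a RefSeq accession. The table of mouse genes used here (assembly GRCm38.p6) matched 13 of the RefSeq accessions, without versions, and named no other probe. The fixed rule was to name Cdx2, the 12 largest rises and 12 largest falls per stage among called genes with a symbol and the same sign in every pair, up to 4 called members of each gene list or its member with the smallest p, the 6 largest changes each way for the stage contrast and the 8 largest each way for the control stages; without calls, the 6 largest each way at an unadjusted p under 0.001 were to be given as values. Since only 13 genes could be named, the 12 that were tested are described by their values. Of 25 gene lists written before the data were examined, 0 had the 5 tested members that the set test (camera) required. The rule, the tests and most alternatives were fixed before the data were examined.

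Sequences shared by probes were sought after the values were seen. All 7-base sequences present in at least 10 of 18723 probes drawn at random were ranked by the z score of the mean blastocyst ratio of the probes that held them, those of the 20 highest that overlapped were joined, and the joined sequence was tested in the other 18723 probes. The sequence had first been seen over all probes and the minimum of 10 was chosen after looking, so the other probes were not unseen. The ratios were also predicted from all 7-base sequences by a penalised linear fit (lsqr of scipy 1.17.1, damping 10), each of 5 parts of the probes from the other parts. The alternatives covered the background correction, the normalization, the filter on dim probes, the treatment of dye-swapped arrays, the variance model, the pairing, the batches and each pair left out in turn. The fits were tested on simulated data for the 37446 probes, in which 100 probes drawn at random were changed 2-fold and 100 changed 4-fold. The noise was normal, independent between probes, and had the spread that the limma fit estimated for each probe. In the measured blastocyst pairs, probes with a mean ratio above 0.5 varied more (median SD 0.532) than those below -0.5 (0.344). The shares recovered below therefore need not hold for such probes. In the simulated 8-cell comparison 35% of the 2-fold and 99% of the 4-fold changes were recovered, in the blastocyst comparison 70% and 98%, in the stage contrast 9% and 90%, and in the comparison of control embryos 24% and 81%. False calls among the unchanged probes were 11, 15, 11 and 4.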

Results

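The series addressed which transcripts change when Cdx2, the homeobox transcription factor of the trophectoderm, is knocked down in mouse preimplantation embryos. Transcript levels were measured on 2-colour microarrays in 8-cell embryos, the stage before the outer and inner cells part, and in blastocysts. There were 2 pairs of control and knockdown extracts at the 8-cell stage and 3 pairs at the blastocyst stage, and each pair was hybridised on 2 arrays with the dyes exchanged. Between 87.6% and 94.3% of the probe spots were well above background in Cy5 and between 84.4% and 93.4% in Cy3. Median spot intensity was 299 to 572.2 in Cy5 and 141.8 to 252.4 in Cy3, with median local background of 71 to 81 and of 48.5 to 59. The ratios below are log2 of knockdown over control, in the direction that the channel labels and array names make likely. Under this direction the authors' deposited summary values run the other way, as control over knockdown.

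The knockdown could not be checked on its target, because no probe of the files could be named as Cdx2 with the gene table used here. The same held for the other trophectoderm genes fixed in advance. What follows rests on the labels for which extract carried the knockdown.

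In 8-cell embryos no probe passed the test between knockdown and control. Nr0b1, an orphan nuclear receptor of the pluripotency network, had a mean ratio of 0.68 ± 0.34 (SE, n = 2 pairs; limma adjusted p = 1), with values of 0.315 and 1.04 in the pairs. Zfp42, the zinc finger protein also known as Rex1 and a marker of pluripotent cells, lay at 0.07 ± 0.15 (SE, n = 2). The de novo DNA methyltransferase Dnmt3a lay at -0.34 ± 0.24 (SE, n = 2) and its cofactor Dnmt3l at 0.17 ± 0.27 (SE, n = 2), and neither passed. Among the 37446 probes tested with limma, 0 passed the adjusted threshold, while 387 higher and 282 lower probes had an unadjusted p under 0.05. The ratios of the 2 pairs correlated at r = -0.195 (Spearman's rho = -0.232) across probes, which are not independent replicates, and the median half-width of the 95% confidence interval was 0.385.

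In blastocysts the named gene with the largest ratio was again Nr0b1, at 1.18 ± 0.28 (SE, n = 3 pairs), or 2.27-fold higher in the knockdown, with values of 0.815, 0.73 and 2.0 in the pairs. It was higher in 3 of 3 pairs. Its limma adjusted p over all probes was 0.127, which did not pass, and 0.0115 adjusted over the list alone, a list of pluripotency genes of which only Nr0b1 and Zfp42 could be named. Zfp42 lay at -0.30 ± 0.13 (SE, n = 3; adjusted p = 0.283, or 0.0533 adjusted over the list alone) and was lower in 3 of 3 pairs. Ubb, which encodes polyubiquitin, lay at 0.91 ± 0.12 (SE, n = 2, since 1 pair had an outlier spot; adjusted p = 0.0787), and 1 of its blastocyst spots was saturated. Its coding sequence is made of repeats that other ubiquitin genes share, so the value is uncertain. Xlr3c and Xlr4b, of the X-linked lymphocyte-regulated family, whose near-identical copies make the values uncertain, lay at -0.33 ± 0.10 and -0.41 ± 0.12 (SE, n = 3; adjusted p = 0.165 and 0.157), and each was lower in 3 of 3 pairs. None of the 12 named genes that were tested passed over all probes.

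**Figure D1:**
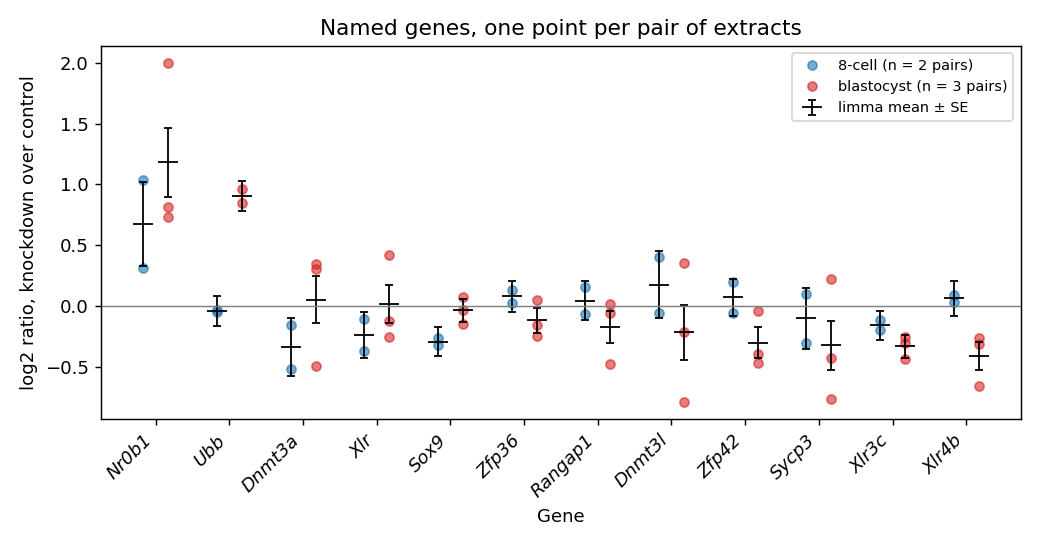
Log2 ratio of knockdown over control (vertical axis) for the 12 named genes that were tested (horizontal axis, ordered by the blastocyst mean), in 8-cell embryos (blue) and blastocysts (red). Each point is 1 pair of extracts averaged over its dye swap, and the black marks are the limma mean ± SE; Ubb has 2 blastocyst pairs. Nr0b1 lies above 0 in all 3 blastocyst pairs, with values of 0.815, 0.73 and 2.0.

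Among all probes, 61 of 37446 were called in blastocysts, and all 61 were higher in the knockdown, with log2 ratios of 1.13 to 2.50 and the same sign in every measured pair. None of them could be given a gene symbol. At an unadjusted p under 0.05 there were 4795 higher and 2050 lower probes, and 3927 probes had a mean ratio above 0.5 against 472 below -0.5. The largest rises among called probes without a saturated spot and measured in all pairs, chosen after the values were seen, were those of TF12788 and TE71053. The probe of TF12788 (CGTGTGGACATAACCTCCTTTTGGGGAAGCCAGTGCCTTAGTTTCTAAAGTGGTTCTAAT) had a ratio of 2.01 ± 0.27 (SD, n = 3; limma adjusted p = 0.0332), or 4.03-fold. The probe of TE71053 (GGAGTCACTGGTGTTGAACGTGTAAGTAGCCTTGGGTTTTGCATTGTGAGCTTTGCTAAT) had a ratio of 1.99 ± 0.48 (SD, n = 3; limma adjusted p = 0.0495), or 3.96-fold. The called probes were bright, with a median log2 signal of 12.58 against 8.16 over all tested probes, and 24 of the 61 were saturated on at least 1 blastocyst array.

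The count of 61 changed with the pairs and with the fit. The limma count was 0 without 8-cell pair 1, 8-cell pair 2, blastocyst pair 1 or blastocyst pair 2, with 5890, 5840, 4000 and 5908 probes at an unadjusted p under 0.05, and 136 without blastocyst pair 3, which left the pairs of 1 extraction day. It was also 0 with blastocysts fitted alone (5910 at an unadjusted p under 0.05) or with control and knockdown extracts as unpaired groups (2995), 1103 with median centring in place of loess, of which 43 were lower, and 2172 with arrays taken singly and the pair as a random block, of which 336 were lower.

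Some of the probes that were higher in knockdown blastocysts also shared a short sequence. Of the 20 7-base sequences with the highest z scores of the mean ratio in 18723 of the probes, 11 lay in the joined 18-base sequence GGGTCTCCAGTGTTTGAC and 4 in its reverse complement. In the other 18723 probes the mean blastocyst ratio was 0.03 ± 0.34 (SD over 14951 probes) where the longest run of this sequence in the probe was 5 bases or fewer, 0.37 ± 0.58 at 7 bases (SD over 770 probes), 0.77 ± 0.68 at 8 (SD over 204 probes) and 0.80 ± 0.69 at 9 or more (SD over 63 probes). Mean log2 signal was 8.69 at 5 bases or fewer and 13.44 at 9 or more. For the reverse complement the mean ratio was 0.05 at 5 bases or fewer and 0.76 at 9 or more (SD 0.38 and 0.61 over 15350 and 60 probes), while mean log2 signal was 8.81 and 9.60. Among the same 18723 probes, 9 of the 38 called ones held 7 or more bases of the sequence or of its reverse complement (23.7%, odds ratio 2.81; Fisher's exact test, two-sided p = 0.0109, with probes as units, which are not independent). The sequence had first been seen over all probes, so these 18723 probes were not unseen and this test is not independent of the search. The 37446 tested probes held 36865 different probe sequences, so identical probes could lie in both parts. Over all probes, including those used for the ranking, 18 of the 61 called ones held a match of 7 or more bases (29.5%), against 10.2% of the others. The other 43 called probes held none of 7 or more bases, but calls were also more frequent at 6 bases. Among the probes left out of the ranking, 17 of 2735 with 6 bases of the sequence were called. At 7 bases 5 of 770 were called, and at 5 or fewer 12 of 14951. The mean ratio at 6 bases was 0.16 ± 0.45 (SD over 2735 probes). Among the 63 and 60 probes above with 9 or more bases of the sequence or of its reverse complement, 0 were called. Probes of the named genes held at most 6 bases of the sequence or of its reverse complement. Since ratios were also higher at 6 bases, this does not clear the named genes of it.

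**Figure D2:**
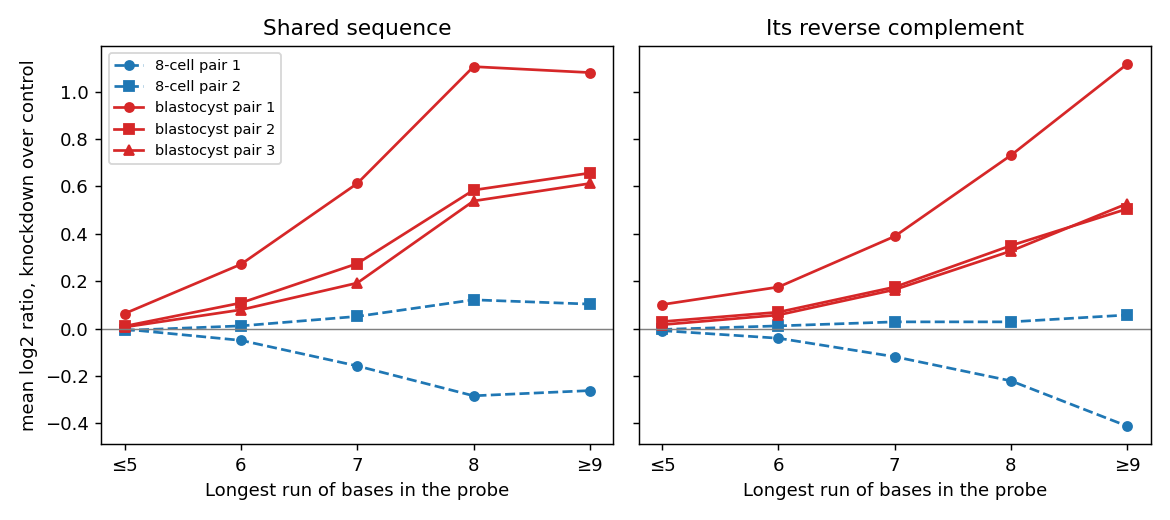
Mean log2 ratio of knockdown over control (vertical axis) by the longest run of bases of the shared sequence in the probe (horizontal axis). The sequence is on the left and its reverse complement on the right. Shown are the probes left out of the ranking, which were not unseen, since the sequence had first been seen over all probes. Each line is 1 pair of extracts, blue and dashed for 8-cell embryos, red and solid for blastocysts. For the sequence itself, blastocyst pair 1 goes from 0.06 at 5 bases or fewer to 1.08 at 9 or more, and 8-cell pair 1 goes to -0.26.

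The knockdown effect was also compared between the stages. No probe passed the limma test of the difference between blastocysts and 8-cell embryos, with 3254 higher and 1056 lower differences at an unadjusted p under 0.05. The ratio of Nr0b1 differed by 0.50 ± 0.44 (SE; adjusted p = 0.753), that of Ubb by 0.95 ± 0.17 (SE; adjusted p = 0.351) and that of Xlr4b by -0.47 ± 0.18 (SE; adjusted p = 0.411). Across the 37446 probes, which are not independent replicates, the mean ratios of the stages correlated at r = -0.315 (Spearman's rho = -0.204). The ratios of 8-cell pair 1 correlated with those of the blastocyst pairs at -0.424, -0.404 and -0.146. For 8-cell pair 2 the correlations were 0.052, 0.018 and 0.16, and without 8-cell pair 1 the stages correlated at r = 0.084. With the sign of 8-cell pair 1 turned they correlated at r = 0.356. Of the probes called in blastocysts, 12 of 61 were higher in the knockdown in 8-cell pair 1 and 29 of the 60 measured were higher in 8-cell pair 2.

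Between the stages, control embryos differed widely. Xlr3c was 2.72-fold higher in control blastocysts than in control 8-cell embryos (log2 difference 1.44 ± 0.16 SE, limma adjusted p = 0.000883), with mean log2 signals of 9.38 ± 0.08 (SD, n = 3) and 7.94 ± 0.20 (SD, n = 2). Xlr4b was 2.77-fold higher (1.47 ± 0.35 SE, adjusted p = 0.0269) and Zfp42 2.43-fold higher (1.28 ± 0.32 SE, adjusted p = 0.0310). Dnmt3l and Nr0b1 had differences of 1.41 ± 0.44 and 1.28 ± 0.42 (SE), which did not pass over all probes (limma adjusted p = 0.0690 and 0.0836). They passed adjusted over the list alone (0.0227 and 0.0153, with 2 members measured in each list). This carries little weight, since 10632 of all 37446 probes had an unadjusted limma p under 0.05 between the control stages. Xlr fell by 0.74 on the log2 scale (SE 0.20, adjusted p = 0.0432). Sox9, a transcription factor of later lineages, was on no array of control blastocysts well above background. Its measured log2 difference was -0.547 (limma adjusted p = 0.0226). The bound, at least 1.36-fold higher in control 8-cell embryos, was not itself tested. Mean log2 signals were 6.52 in control 8-cell embryos and 5.97 in control blastocysts, near the floor of 6.07. Sox9 entered the test only through the control 8-cell group, where it was high. Dnmt3a, Sycp3, Rangap1, Zfp36 and Ubb did not pass. With each pair left out in turn, Xlr3c passed every time. Xlr4b missed the threshold without 8-cell pair 1 (limma adjusted p = 0.0680) and without blastocyst pairs 1, 2 or 3 (0.0522, 0.132 and 0.0945), and Zfp42 without 8-cell pair 1 (0.107) and blastocyst pairs 2 or 3 (0.121 and 0.101). Xlr missed it without every pair but blastocyst pair 2 (up to 0.185), with the extraction day (0.0915) or the pair of extracts (0.0695) as a random block, and with quantile normalization of all channels (0.0527, or 0.0714 from processed signals). Sox9 missed it without any of the pairs (up to 0.101).

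**Figure D3:**
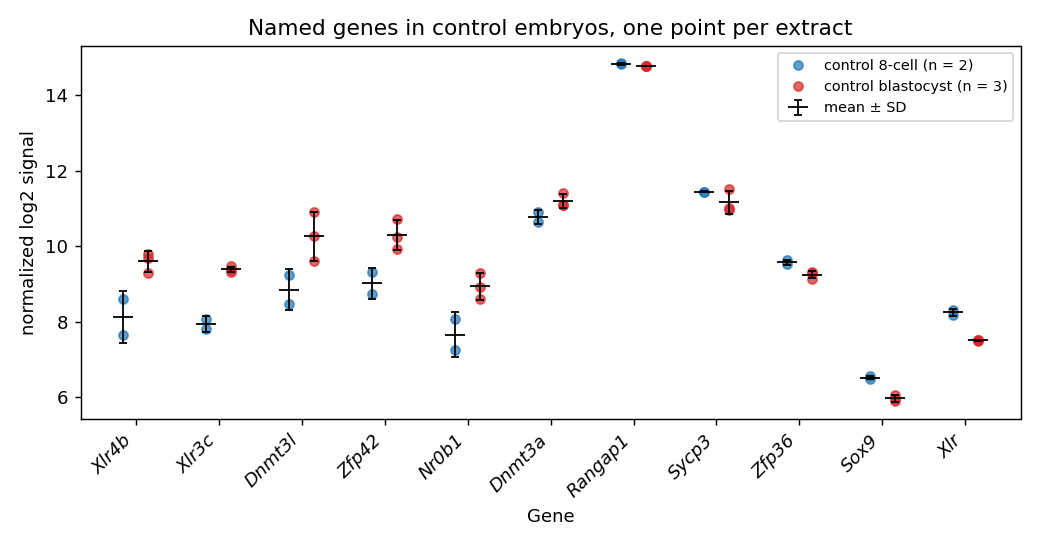
Normalized log2 signal (vertical axis) of 11 named genes (horizontal axis) in control 8-cell embryos (blue, n = 2) and control blastocysts (red, n = 3). Each point is 1 extract averaged over its dyes and black marks are mean ± SD; levels of different genes are not comparable. Xlr3c goes from 7.94 to 9.38 and Zfp42 from 9.01 to 10.29.

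Over all probes, 5067 of 37446 differed between the control stages, 2507 higher and 2560 lower in blastocysts, and 1684 and 1721 of these by at least 2-fold. The largest falls among probes above background in every stage and condition, chosen after the values were seen, were those of TF15128 and TB16056. TF15128 had a mean log2 signal of 12.66 in control 8-cell embryos and 7.48 in control blastocysts, or 36.3-fold lower (limma adjusted p = 0.000215), and TB16056 went from 11.92 to 7.08, or 28.5-fold lower (limma adjusted p = 0.000152). The control stages were hybridised on different arrays, whose scans were extracted on different days. With the day as a random block 3855 probes passed, and with 8-cell pair 2, blastocyst pair 2 or blastocyst pair 3 left out 3374, 2073 and 2817.

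Of the gene lists fixed in advance, only those of pluripotency genes, epigenetic regulators and cumulus cells had a member that could be named. Of the pluripotency genes, 0 of 2 tested members passed over all probes at either stage. Adjusted over the list alone, 0 of 2 passed in 8-cell embryos and 1 of 2, Nr0b1, in blastocysts. That adjustment spans only 2 genes, and 6845 of all 37446 probes had an unadjusted limma p under 0.05 in blastocysts. A pass over the list alone therefore carries little weight. For the knockdown, 0 of 2 epigenetic regulators, Dnmt3a and Dnmt3l, passed at either stage, either over all probes or adjusted over the list alone, where the limma adjusted p was 0.794 and 0.740 in blastocysts. Ptgs2, the prostaglandin synthase that stood for cumulus cells, was on no array of blastocysts well above background and was not tested. The other lists, among them trophectoderm, primitive endoderm, fibroblasts, spermatozoa and blood cells, had 0 members that could be named, so the composition of the samples was not examined.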

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

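Ubb and Xlr4b stood out among the named genes because their ratios lay on opposite sides of 0 in the 2 stages in every measured pair. For Ubb they were -0.031 and -0.048 in the 8-cell pairs and 0.966 and 0.85 in the 2 measured blastocyst pairs. The difference, blastocyst minus 8-cell, was 0.948 on the log2 scale. Under the alternatives it ranged from 0.409, with the part predicted from sequence subtracted, to 1.171. For Xlr4b the ratios were 0.089 and 0.037 in the 8-cell pairs and -0.311, -0.659 and -0.266 in the blastocyst pairs, with a difference of -0.475. Neither difference passed (limma unadjusted p = 0.0029 and 0.0404, adjusted p = 0.351 and 0.411 over all probes). The 8-cell values were small, and their means lay within their limma SE of 0 (0.12 for Ubb and 0.14 for Xlr4b). These SEs rest on a spread shared by both stages. The SD between the 2 8-cell pairs alone was 0.012 for Ubb and 0.037 for Xlr4b. With 2 pairs and values this small, the 8-cell signs carry little weight. How many of the 12 named genes would show this pattern by chance was not tested. For both genes it also rests on the direction of 8-cell pair 1. If its labels were swapped, which stays open, the 8-cell pairs would have opposite signs for each gene. Groups of 2 and 3 pairs are too small for a test of single samples far from the others.

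A signal also appeared in a feature outside the comparisons, spotted 99 times on each array, whose accession the mouse gene table does not hold. On the median array 98.5% of its spots were well above background in Cy5, against at most 2.87% of the 314 negative-control spots on any array, and the share ranged from 10.1% to 100% between arrays. Its highest median Cy5 intensity was 153, against 102.4 for the negative controls. The other such feature, spotted 98 times, had a median of 3.6%.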

How the results depend on the processing

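Alternatives that used the shared sequence, the saturation, the turned sign of 8-cell pair 1, the looser rule for pairs, or the pair as a random block of the extracts were chosen after seeing the data; the others were planned. At the 8-cell stage the count of called probes was 0 under every alternative run. In blastocysts the 61 calls became 636 with the scanner's processed signals, 1126 with normexp offset 0, 1103 with median centring, 159 with an intensity trend in eBayes, 2172 with arrays taken singly and the pair as a random block, 2998 with a dye term added, 1422 with only the arrays that had the knockdown in Cy5, 595 with the sign of 8-cell pair 1 turned, 134 with the part predicted from sequence subtracted, 92 with pairs of 1 usable array kept and no minimum of pairs, and 24 without probes saturated on any array. Lower in the knockdown were 12 of the 636, 17 of the 1126, 43 of the 1103, 1 of the 159, 336 of the 2172, 275 of the 2998, 143 of the 1422, 27 of the 595, 4 of the 134 and 0 of the 92 and the 24. The calls became 0 with no filter on dim probes, with only the arrays that had control in Cy5, with each stage in its own fit, and with no replicate block (single channels unpaired). With single pairs left out the count ranged from 0 to 136. Taking arrays singly treats dye swaps as partial replicates, and leaving out pairs lowers the residual degrees of freedom. The cause of the changed counts was not tested for these or for the other alternatives. Leaving out blastocyst pair 3 also lowers the degrees of freedom, yet there the count rose to 136, with 31 of them among the 61. The stage contrast had 0 calls except 2 with arrays taken singly and 29 with a dye term added. The correlation between the stages (-0.315) turned to 0.138 with only the arrays that had the knockdown in Cy5 and to 0.356 with the sign of 8-cell pair 1 turned, and ranged from -0.43 to 0.084 with single pairs left out. In the authors' value table it was -0.258 over the probes tested here and -0.222 over the whole table. The 5067 calls between control stages became 4647 to 5045 under other normalizations and filters, and 2073 to 4241 with single pairs left out, where a lone 8-cell pair is assumed to vary like the others. Of 1005 values of named genes under alternatives, 980 kept their side of the threshold, 5 passed only under the alternative and 20 passed only in the reported fit. None that passed changed its sign. Most of the 1005 belonged to comparisons that did not pass in the reported fit, so the 980 say little about the calls. The calls were control stage changes with 11 alternatives each. Xlr3c passed in 11 of them, Zfp42 in 8, Xlr4b in 7, Sox9 in 6 and Xlr in 3. Nr0b1 in blastocysts stayed between 0.772 and 1.407, with adjusted p between 0.00778 and 0.432. Ubb in blastocysts ranged more widely, from 0.412 to 1.165, with adjusted p between 0.0276 and 0.542. It passed under 2 of its 22 alternatives. Not run were the gene list tests and the check on Cdx2, for want of named probes. The day as a block of the ratios was left out too, since the fit gave no estimate for it. Only 1 day held more than 1 pair. The mean over probes of a gene joined 2 pairs of probes and changed no call. The pairing is by shared arrays, and the unpaired fit changed no other call of a comparison between knockdown and control. With the pair of extracts as a random block 4775 probes passed between the control stages, 4478 of them among the 5067, and of the named genes the call of Xlr ended (limma adjusted p = 0.0695). Signal over background limits the dim probes: of 41819 probes 37878 were well above background in some stage and condition.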

Other observations

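The tests of loess, of signal by shared bases, of flanking bases, of the reverse complement, of the imbalance in blastocysts by sequence, of turned signs and of the 8-cell pairs in probes where sequence matters least, and the alternatives with the shared sequence left out or subtracted, were chosen after the result was seen. The shared sequence itself had first been seen over all probes.

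The hypothesis that knockdown blastocysts lagged behind control blastocysts in development was tested through the change from control 8-cell embryos to control blastocysts, taken from the other pairs. A common lag predicts ratios that run against this change in every pair. Across probes the correlations were -0.09 and -0.211 in blastocyst pairs 1 and 2 and 0.136 in pair 3, so the highest, 0.136, argues against a lag common to the 3 pairs.

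The number of saturated spots in blastocysts differed between the conditions in Cy3 and less so in Cy5. With the knockdown extract in Cy3, 464, 368 and 248 spots were saturated in Cy3 on the arrays of pairs 1, 2 and 3, and with the control extract in Cy3 they were 53, 41 and 69. In Cy5 the numbers were 838, 815 and 608 with the knockdown and 664, 614 and 629 with the control, so pair 3 went the other way there. At the 8-cell stage the Cy3 numbers were 255 and 67 with the knockdown and 278 and 126 with the control, and the Cy5 numbers were 848 and 705 with the knockdown and 1180 and 610 with the control.

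The first pattern is the sequence shared by some of the probes that were higher in knockdown blastocysts. A repeat element or gene family would extend beyond the shared bases, but over the 20 flanking positions of 158 probes with 9 or more bases of it the most common base reached at most 38.7%, against 29.2% for the most common base overall. Repression of matching transcripts by a small RNA in control embryos would act on 1 strand. Yet probes with 7 or more bases of only the reverse complement were also higher, by 0.318 (SE 0.0185 over probes, not over embryos). Labelled material that binds unrelated probes through a short sequence, and differs in amount between extracts, may be a source, but signals of different probes do not decide it: at 9 or more bases mean log2 signal exceeded that at 5 or fewer by at least 4.2 in each of the 10 extracts for the sequence, and by only 0.428 to 1.54 for its reverse complement. What such material would be was not tested, and an effect of the knockdown on the transcripts stays open.

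The second pattern is that more probes were higher than lower in knockdown blastocysts, by 8.32 to 1 beyond 0.5 on the log2 scale. Its side rests on the direction taken from the labels. With that direction turned, the excess and all 61 calls would be lower in the knockdown. Loess is argued against as the cause, since 3.9% of the calls were lower with median centring, while the SD between pairs of lower probes, at the median 0.646 times that of higher probes, decides nothing, as a larger spread would have added lower probes. Labelled material that binds probes through a short sequence may be a source, but an imbalance stayed with the part predicted from sequence subtracted. There were then 3251 probes above 0.5 and 784 below -0.5, a ratio of 4.15, with 130 higher and 4 lower calls. Among probes with 5 or fewer bases on both strands, 659 lay above and 171 below. Without probes sharing 7 or more bases there were 42 higher and 0 lower calls. Probes with 6 bases stayed in that set, so this count is not free of the sequence. Their mean ratio was 0.16, against 0.03 at 5 or fewer, among the probes left out of the ranking. Other values go with such material. Of 10 equal groups by predicted ratio the lowest had 32 above and 83 below. The highest had 1610 and 15 and held 33 of the 61 calls. The probes with 5 or fewer bases in the lowest 5 groups had 152 and 121. Neither side decides it, since grouping by a prediction of the ratios orders them under any cause and the subtraction overshot in the lowest group (126 above and 0 below after it), so this material cannot be told apart from an effect of the knockdown.

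The third pattern is the negative correlation of the 8-cell pairs (-0.195). Between single arrays of the 2 pairs, as knockdown over control, it was 0.201 and 0.005 with the same dye orientation. With the opposite orientation it was -0.442 and -0.298. Whether a dye effect that did not fully cancel contributes was not tested. Timing that differs in opposite directions predicts correlations of opposite sign with the stage change. These were 0.137 in pair 1 and 0.005 in pair 2, with a product of 0.0007. Pair 2 lay so near 0 that the sign of the product decides nothing, so such timing stays open. Probes with 9 or more bases of the sequence differed from those with 5 or fewer by -0.259 in pair 1 (SE 0.0477). In pair 2 they differed by 0.111 (SE 0.0666), not clearly from 0. Both SEs are over probes and hold no spread between embryos. An opposite excess of labelled material may therefore account for a part, but is not shown. As the whole cause it is argued against, since the correlation was still -0.178 with the predicted part subtracted, -0.18 with that part scaled to the ratios first, -0.177 in the 24234 probes with 5 or fewer bases on both strands and -0.19 in the 7494 with predictions closest to 0, though the prediction was incomplete (r = 0.336 and 0.228). A swapped label in 1 pair cannot be told apart from a difference between embryos: with the sign of pair 1 turned 0 probes passed at the 8-cell stage (2077 at an unadjusted p under 0.05), and no probe of the targeted gene could be named to decide it.

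For the 61 calls in blastocysts, turning the sign of 1 of the 3 pairs gives only 4 patterns, too few for a share under 0.05. As measured 61 probes passed, the highest count of the others was 0, and 1 pattern of the 4 reached as many.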
